A study of Bos taurus with 10 samples.

How the data were processed

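Poly(A)-selected RNA was sequenced from pools of bovine embryos whose zygotes had been injected with small interfering RNA against H1FOO, the linker histone of the oocyte (knockdown, KD), or with negative control small interfering RNA (NC). Embryos were collected at the 8/16-cell stage, 4 days after insemination, with 2 libraries per treatment, and at the morula stage, 5.5 days after insemination, with 3 libraries per treatment. All 10 libraries were used, every data column was matched to its sample by treatment, stage and replicate, and 0 columns were left unmatched.

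Per the labels' protocols, RNA was isolated with a Picopure kit, messenger RNA was taken up on oligo(dT) beads, and libraries were made with an NEBNext Ultra kit and amplified by PCR. The labels do not say whether the libraries keep strand, so reads of a gene and of an antisense partner cannot be told apart. Per the submitters' processing notes, Trimmomatic, HISAT2, featureCounts and Cufflinks were used with the builds ARS-UCD1.2 and bosTau9; neither versions nor the step each tool served are given. The deposited values are FPKM (fragments scaled by gene length and by the mapped fragments of the library), in a gene by library table of 39911 lines. No table of raw counts was analysed, so the read depth of each library and the counting error of each value are unknown. The most common ratio between the lowest values of a library and those of NC 8/16-cell replicate 1, read as 1 fragment against 1 fragment, would put the relative depths between 0.71 and 1.44.

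The table holds 28781 distinct gene symbols. For 81 symbols that stand for several loci (11211 lines), the morula columns pair every locus with every other while the 8/16-cell columns repeat 1 value. The columns of the 2 stages were therefore probably made apart and merged, and comparisons between stages carry any difference in how they were made. These 81 symbols were left out, which left 28700 genes. The 13 genes of the mitochondrial genome are listed at 0 in every library. Symbols were compared with an annotation of another build, ARS-UCD2.0, for names only, and no coordinates were taken.

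FPKM values were transformed to log2(FPKM + 1), and the 11761 genes with a mean of at least 1 FPKM over all libraries were tested. The limma package (version 3.58.1, in R 4.3.3) fitted the 4 group means to all 10 libraries at once, with limma-trend moderation of the variances (6 residual degrees of freedom, 4.63 prior degrees of freedom). Two-sided p-values were adjusted by the Benjamini-Hochberg method over all genes tested, and a gene passed at an adjusted p under 0.05. The comparisons were KD against NC at each stage, the difference between those effects (interaction), and morula against 8/16-cell embryos within each treatment. The p-values measure only the spread between these libraries. FPKM is a share of a library, so all changes are relative to the other transcripts of the same library.

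Genes were named by a rule fixed before the data were examined. For KD against NC it took the 10 largest rises and falls among genes that passed, whose KD and NC libraries did not overlap, with a mean of at least 5 FPKM at that stage and a gene symbol. Where fewer than 10 qualified, it filled up to 10 with the smallest p among genes meeting the other conditions, which are said not to pass; 1 of these at the morula stage is not described. It added H1FOO, the lineage genes NANOG, SOX2, POU5F1, CDX2, GATA3, GATA6, TFAP2C, KRT8, KRT18 and SOX17, up to 4 members of a described list by smallest p, and the 5 largest rises and falls between the NC stages.

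In the same way 27 gene lists were fixed: the target; other linker histones; core histones; histone variants; nucleosome assembly chaperones; chromatin modifiers; DNA methylation; inner cell mass and epiblast; primitive endoderm; trophectoderm; Hippo, polarity and cell junctions; oocyte transcripts; genome activation; DNA replication and cell cycle; p53 and apoptosis; stress and heat shock; interferon response; FGF, BMP, Nodal and Wnt signalling; ribosomal proteins; ribosome biogenesis; mitochondrially encoded genes; oxidative phosphorylation; glycolysis; imprinted genes; cumulus and granulosa cells; sperm and testis; blood and immune cells. The last 3 and the oocyte list hold markers of other cells that a pool could carry. The 25 lists with at least 3 tested genes were tested with camera (limma, preset correlation 0.01, Benjamini-Hochberg over the lists of a comparison) and again with an estimated correlation. Genes of a list were also counted with p-values adjusted over the list alone.

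The treatments share replicate numbers within a stage, and the labels do not say that a number marks a shared collection. At the morula stage, the deviations of same-numbered KD and NC libraries from their group means correlated across genes in all 3 pairs (r = 0.37, 0.325 and 0.312). The numbers were therefore taken to pair these libraries. A fit with the replicate number as a block is given beside the morula and interaction results whose call it changes. Deviations from a mean of 3 libraries sum to 0, so these 3 values are not independent. With few ways to match 3 libraries to 3, the numbered match could be the best one by chance. The pairing is thus inferred from the same data as the blocked calls. The block also leaves fewer residual degrees of freedom than the 6 of the main fit.

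Alternatives were other pseudocounts and filters, quantile normalization, median scaling, rescaling to an equal sum, stages fitted alone, the block, other moderation of the variances, library weights, a 2-fold minimum and leaving out each library in turn. Data were simulated with the libraries' own means and spread, with 5 draws of 100 changed genes per fold. The changed genes were drawn only from genes of higher level, and all genes varied independently. The fit over 11761 genes recovered 35.4% of 2-fold and 96.4% of 4-fold changes at the 8/16-cell stage, and 66.6% and 99% at the morula stage. Of the calls at those stages 4.08% and 5.91% were false. Recovery for genes of low level was not measured. The share recovered also depends on how many genes change, since the Benjamini-Hochberg cutoff is stricter when fewer do. It is therefore no measure of what would be found at the 8/16-cell stage. There 2 genes passed, and H1FOO at a log2 difference of -4.22 did not (limma adjusted p 0.104). Of 200 simulated lists of 20 unchanged genes, camera with the preset correlation put 2% under 0.05. These lists were drawn at random from genes that varied independently. The estimated correlation of the real lists reached 0.247 for core histones and 0.825 for ribosomal proteins. The 2% therefore does not cover lists whose genes vary together.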

Results

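The 10 libraries covered NC and KD embryos at the 8/16-cell stage (2 libraries each) and at the morula stage (3 libraries each). The summed FPKM per library ran from 345464 to 669836, and 11103 to 11872 genes reached 1 FPKM. The first principal component of the tested genes held 50.1% of the variance and separated the stages, and the second held 12.8%. Pearson correlations across genes were 0.938 to 0.971 between libraries of a group, 0.884 to 0.972 between treatments within a stage and 0.814 to 0.922 between stages. Per its title, the series asks what H1FOO contributes to early bovine development, to the setting up of cell lineages and to nucleosome assembly.

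H1FOO, the oocyte's own linker histone and the target of the injected RNA, was lower in KD than in NC embryos in every library of both stages. At the 8/16-cell stage it stood at 50.8 and 10.8 FPKM in the NC libraries and at 0.649 and 0.0736 FPKM in the KD libraries. The log2 difference was -4.22 (SE 0.60, n = 2 per group), with a limma adjusted p of 0.104 over all genes, so the target did not pass the genome-wide threshold there. Without NC 8/16-cell replicate 2 the difference was -5.28 with an adjusted p of 0.00353, a fit in which 1 NC library is left and is assumed to vary like the other groups. Over the alternatives run the adjusted p ranged from 0.00353 to 0.662. By the morula stage H1FOO was low in both treatments, at 0.294, 1.05 and 2.17 FPKM in NC and 0.0610, 0.191 and 0.251 FPKM in KD libraries (log2 difference -0.80, SE 0.49, n = 3 per group, adjusted p 0.374).

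**Figure D1:**
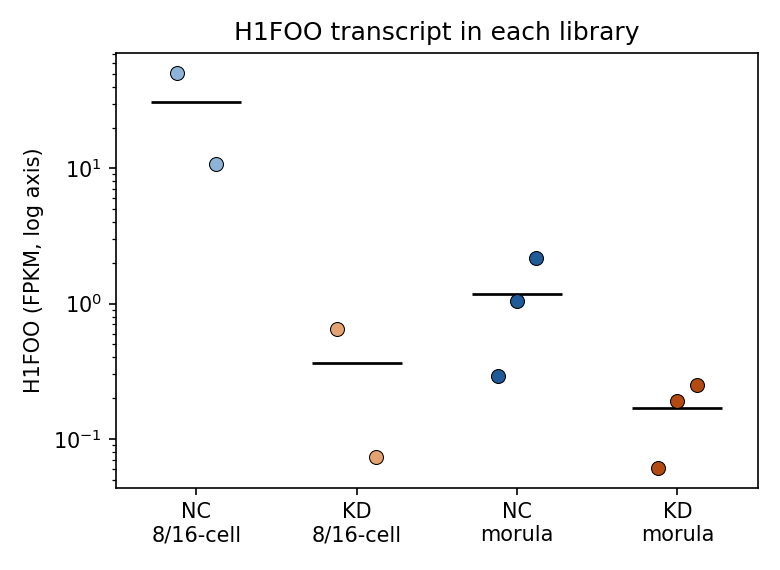
H1FOO in FPKM on a log axis for each library (points) of the 4 groups, with the group mean (line). The KD libraries of the 8/16-cell stage lie at or below 0.649 FPKM and the NC libraries at or above 10.8 FPKM; at the morula stage the highest library reaches 2.17 FPKM.

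At the 8/16-cell stage the 2 genes that passed were the microRNA genes MIR2887-1 and MIR2887-2. They were listed at 0 in both NC libraries and in all 6 morula libraries. They reached 45345.5 and 136037 FPKM in KD 8/16-cell replicate 1 and 18126.6 FPKM each in KD replicate 2, and MIR2887-2 held 20.31% of the summed FPKM of KD replicate 1. By their shared name they are copies of 1 microRNA gene, so the split of reads between them is uncertain. FPKM divides by gene length, so a few fragments on a gene as short as these could give values this large. The number of fragments behind them is unknown. The 20.31% is a share of summed FPKM and not of reads, and how much this microRNA differed is not shown. LTC4S, which makes leukotriene C4, stood at 1.11 FPKM in NC and 19.3 FPKM in KD (log2 difference 3.43, SE 0.70), and IER3, an early response gene linked to cell survival, at 85.6 and 38.1 FPKM (-1.16, SE 0.23), but neither passed (adjusted p 0.576 and 0.481). The same holds for CBY1 (0.76), CALD1 (1.18), SGK1 (0.71), GSN (1.04), INHBB (1.11), MRO (3.13) and AMACR (1.12) above NC, and for MTCL1 (-1.0), SYNE1 (-1.16), GK (-0.75), GM2A (-0.67), SP6 (-0.78), TTC9C (-0.75), SNAP25 (-0.89) and FOXI3 (-0.82) below it, all log2 differences.

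In limma, 2 of 11761 genes passed at this stage, the MIR2887 pair, and 514 had an unadjusted p under 0.05. A total of 3907 genes (33.2%) had KD and NC values that did not overlap, where chance gives 33.3% on average over splits of the libraries. Leaving out NC replicate 2 or KD replicate 2 gave 7 and 9 genes, and without the MIR2887 pair, with each library rescaled to an equal sum, no gene passed (limma 0, with 412 at an unadjusted p under 0.05).

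Several gene groups lay to 1 side at the 8/16-cell stage without a member that passed. Transcripts of ribosomal proteins were higher in KD for 82 of 83 genes (median log2 difference 0.22, camera adjusted p 0.000126), and those of oxidative phosphorylation for 70 of 78 (0.24, 0.000106). Oocyte transcripts, H1FOO among them, were lower for 28 of 33 genes (-0.24, 0.000106), and inner cell mass and epiblast genes for 19 of 21 (-0.14, 0.00494). Higher medians were also found for interferon response genes (0.59, 14 of 15 genes, 0.00919), glycolysis (0.22, 15 of 20 genes, 0.0152) and markers of cumulus and granulosa cells, the somatic cells around the oocyte (0.51, 11 of 17 genes, 0.0125). With an estimated correlation the adjusted p of these 7 lists lay between 0.722 and 0.911, so none of the calls held. With fry, the shift to 1 side had an adjusted p of 0.874 for each of the 7.

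Rescaling each library to an equal sum moved the median of all genes at this stage from 0.01 to -0.35, because of the MIR2887 values, and turned the medians of ribosomal proteins (-0.18), oxidative phosphorylation (-0.13) and glycolysis (-0.07) negative. Each of the 7 calls was lost without at least 1 library: without KD replicate 1 the adjusted p was 0.832 for ribosomal proteins, 0.866 for oxidative phosphorylation and 0.0964 for glycolysis; without NC replicate 1 it was 0.109 for oocyte transcripts (median 0.01), 0.249 for inner cell mass genes and 0.192 for interferon genes; without KD replicate 2 it was 0.135 for cumulus genes. The other 18 lists had camera adjusted p-values between 0.0981 and 0.939, among them core histones (0.891) and other linker histones (0.502). Among lineage genes SOX2 stood at 102 FPKM in NC and 62.6 FPKM in KD (-0.68) and KRT18 at 13.2 and 2.98 FPKM (-1.85). NANOG (-0.14), POU5F1 (-0.25), CDX2 (-0.81), GATA3 (-0.62), GATA6 (-0.33), TFAP2C (-0.17), KRT8 (0.19) and SOX17 (-0.53) also had log2 differences with limma adjusted p-values of 1.

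At the morula stage the histone genes H1FX and HIST2H2BE rose in KD embryos, and the junction genes DSP, PERP and CLDN10 fell. H1FX, a linker histone made in most somatic cells, rose from 40.6 FPKM in NC to 109 FPKM in KD (log2 change 1.36, SE 0.22, adjusted p 0.0374), and HIST2H2BE, a core histone H2B gene, from 27.0 to 52.3 FPKM (0.94, SE 0.18, adjusted p 0.0486). The calcium-binding protein S100A14 dropped from 103 to 17.0 FPKM (-2.49, SE 0.40, adjusted p 0.0374). DSP, which ties keratin filaments to desmosomes, moved from 8.23 to 1.98 FPKM (-1.64, SE 0.23, adjusted p 0.0294), with n = 3 per group throughout. The 18S ribosomal RNA gene RN18S1 stood at 2704, 2983 and 8611 FPKM in the NC morulae and at 9053, 8553 and 11581 FPKM in the KD morulae, a log2 difference of 1.23 (SE 0.50) that did not pass (adjusted p 0.194; blocked 0.0386).

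Other named genes that fell were CPNE3, a calcium-dependent membrane-binding protein (-2.19), PERP, a desmosomal p53 target (-2.07), the tight junction gene CLDN10 (-1.98), the proton pump subunit ATP6V0A4 (-1.90), SEMA4C (-1.77), C6H4orf19 (-1.74), LMBRD1, which carries cobalamin out of lysosomes (-1.73), and ACSS1, a mitochondrial acetyl-CoA synthetase (-1.61). GSTM3, a glutathione transferase, rose from 17.6 to 40.2 FPKM (1.15, SE 0.17, adjusted p 0.0298). The linker histone H1F0 (1.65), TNFAIP1 (1.33), ZNF280A (1.03), the clock gene PER1 (0.90), the kinase SGK1 (0.73) and ZSCAN5B (2.09) were higher in all 3 KD libraries without passing (adjusted p 0.056 to 0.0587), and passed in the blocked fit.

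**Figure D2:**
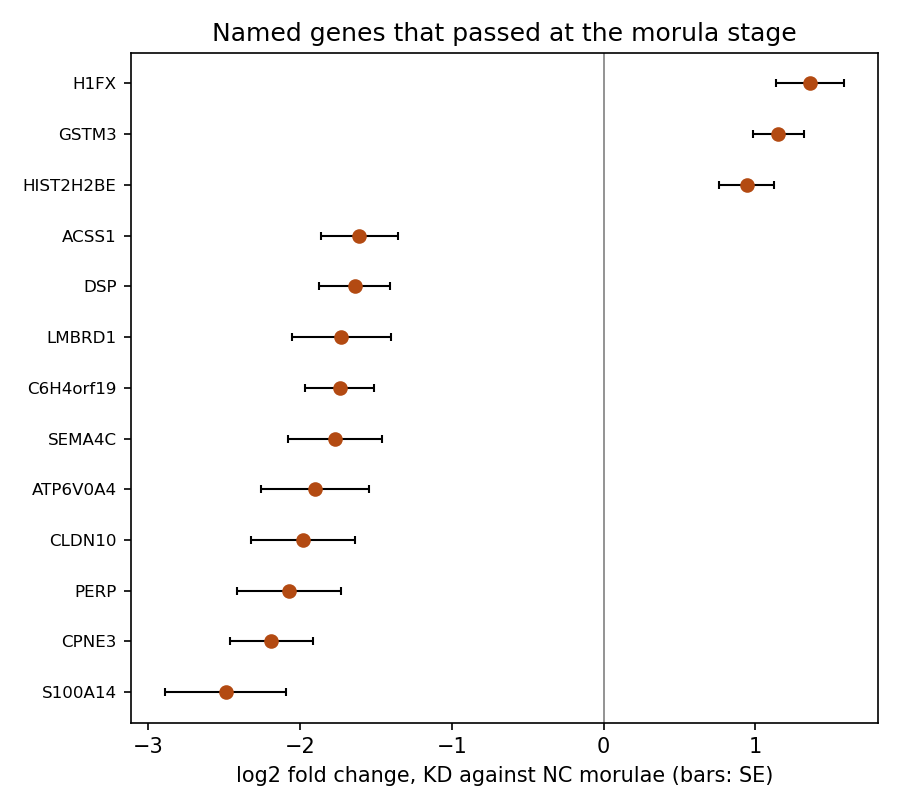
Log2 fold change of KD against NC morulae (x axis, n = 3 per group, bars are standard errors) for the named genes that passed in limma (y axis). The lower genes run from S100A14 at -2.49 to ACSS1 at -1.61 and the higher genes from HIST2H2BE at 0.94 to H1FX at 1.36.

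In limma 82 of 11761 genes passed at the morula stage, 17 higher and 65 lower in KD, and 15 and 52 of these changed at least 2-fold. At an unadjusted p under 0.05 there were 2491 genes. KD and NC values did not overlap for 2795 genes (23.8%), where chance gives 10% on average over splits of the libraries. Genes vary together, so 1 split can lie far from that average by chance, and the share under other splits was not measured. The blocked fit called 1398 genes (457 higher, 941 lower), all 82 among them. The 82 adjusted p-values lay between 0.0243 and 0.0486, just under the threshold. The count was 0 without NC morula replicate 1 or KD morula replicate 2 (limma, with 1687 and 1771 genes at an unadjusted p under 0.05), 1 without NC replicate 3, 2 without KD replicate 3, 41 without NC replicate 2 and 527 without KD replicate 1. It was also 0 without any 1 of the 8/16-cell libraries (2252 to 2405 unadjusted), with the morula libraries fitted alone (2131 unadjusted) and with RN18S1 as a covariate (1243 unadjusted); the blocked fit without the libraries numbered 1 gave 0 as well (2449 unadjusted). With the covariate all 82 genes kept their sign, while the median size of their log2 change went from 1.29 to 1.14 and the median SE from 0.22 to 0.28.

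Of 20 core histone genes 19 had a positive difference (median 0.94), 1 rose over all genes tested, and 8 rose when adjusted over the list alone; the camera adjusted p was 4.11e-08. Of 7 other linker histones all had a positive difference (median 1.09), 1 rose, and 4 rose when adjusted over the list alone (camera adjusted p 1.17e-05). For both lists the adjusted p was 0.529 with an estimated correlation, and the blocked fit called 11 and 5 of their genes. With fry, the shift to 1 side did not pass for either list (adjusted p 0.12), and no other list had a lower value at this stage. Changes in either direction passed with fry for core (0.0062) and other linker histones (0.00682). HIST1H1C stood at 35.2 FPKM in NC and 137 FPKM in KD (log2 difference 2.04, adjusted p 0.0617), and HIST1H2BN (1.57), HIST1H2BI (1.37), HIST2H2AA4 (1.15) and HIST1H1B (1.10) were also higher without passing. Copies of histone genes are alike enough to share reads, so values of single copies are uncertain. Per library, the mean log2 level of the 27 histone genes was 2.58, 3.43 and 3.40 in NC and 3.84, 4.04 and 4.30 in KD morulae, beside the higher RN18S1 values of the KD libraries.

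**Figure D3:**
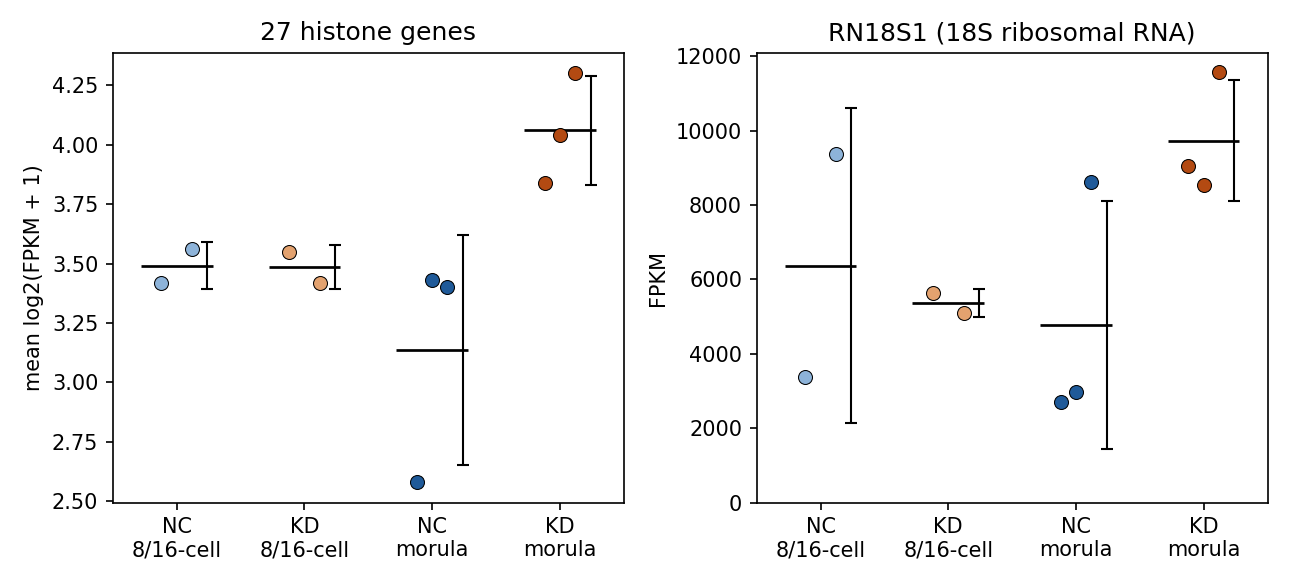
Mean log2(FPKM + 1) of 27 core and linker histone genes (left) and FPKM of RN18S1 (right) in each library (points) of the 4 groups, with the group mean (line) and SD (bar). The KD morulae lie at 3.84 to 4.30 for the histone mean against 2.58 to 3.43 in the NC morulae, and at 8553 to 11581 FPKM against 2704 to 8611 FPKM for RN18S1.

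Nucleosome assembly genes were not called as a group by camera. With fry, their shift to 1 side did not pass (adjusted p 0.221), while changes in either direction did (0.0062), as for most lists. Of 39 nucleosome assembly chaperones 27 had a negative difference (median -0.18, camera adjusted p 0.406), and 1 fell: NASP, a chaperone of linker and core histones, went from 88.7 to 40.3 FPKM (-1.12, SE 0.18, adjusted p 0.0374). When adjusted over the list alone, 3 chaperones fell, and the blocked fit called 2 higher and 7 lower. ANP32E, which removes H2A.Z from chromatin (-1.13), NAP1L4 (-0.78) and ANP32B (-0.67) did not pass over all genes. Histone variants (median -0.17, camera adjusted p 0.577), with H3F3A at -0.74, CENPA at -0.62, H2AFX at 0.57 and H2AFY at 0.33, chromatin modifiers (median -0.09, camera adjusted p 0.406) and DNA methylation genes (median 0.07, camera adjusted p 0.42) were not called as lists. Of 46 chromatin modifiers 1 fell over all genes tested and 3 when adjusted over the list alone. Of 8 histone variants 2 fell when adjusted over the list alone. The blocked fit called 1 histone variant higher and 2 lower, 6 chromatin modifiers lower, and 1 DNA methylation gene in each direction. With fry, changes in either direction passed for histone variants (adjusted p 0.0062) and chromatin modifiers (0.0251), and not for DNA methylation genes (0.183).

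Single genes of the first cell lineages lay to different sides in KD morulae, none of them past the threshold without the block. CDX2, the transcription factor of the trophectoderm, stood at 9.17 FPKM in NC and 1.82 FPKM in KD (log2 difference -1.83, SE 0.36, adjusted p 0.0559; blocked 0.0151), and GATA3 at 4.23 and 0.883 FPKM (-1.32, adjusted p 0.103; blocked 0.0335). The epiblast gene NANOG stood at 13.2 FPKM in NC and 34.1 FPKM in KD (1.39, SE 0.34, adjusted p 0.0724; blocked 0.00506), and POU5F1 at 559 and 377 FPKM (-0.60, adjusted p 0.264; blocked 0.0329). SOX2 (-0.15), GATA6 (-0.34), TFAP2C (0.00), KRT8 (-0.99), KRT18 (-0.59) and SOX17 (-0.32) did not pass in either fit. None of these differences was shown to vary between the stages, with interaction adjusted p-values of 0.479 for NANOG and 0.585 for CDX2.

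As lists, trophectoderm genes had a median of -0.27, with 1 of 18 genes (DSP) that fell and 4 when adjusted over the list alone (camera adjusted p 0.463; 1 higher and 4 lower in the blocked fit), and MSX2 at -1.90 did not pass. Inner cell mass genes had a median of -0.23 (camera adjusted p 0.432; 2 higher and 3 lower in the blocked fit), with OTX2 at -1.67, LIN28A at -1.20 and KLF17 at 0.92. Of 18 primitive endoderm genes 13 had a negative difference (median -0.36), with FN1 at -2.66 and DAB2 at -1.40; none passed over all genes (limma adjusted p 0.0513 and 0.0503 for those 2), 6 fell when adjusted over the list alone, and the camera adjusted p was 0.0703 (blocked 0.0229, with 2 genes higher and 7 lower). COL4A1 (-1.0) and LAMB1 (-1.02) of the same list did not pass.

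Of 40 Hippo, polarity and junction genes 32 had a negative difference (median -0.31, camera adjusted p 0.0117), with adjusted p = 0.721 with an estimated correlation. None passed over all genes; 5 fell and 1 rose when adjusted over the list alone, and 10 fell in the blocked fit. Among them were the polarity kinases PRKCI (-1.61) and PRKCZ (-0.95) and the tight junction gene CLDN4 (-1.75). The call was lost without NC morula replicate 1 (adjusted p 0.0751), NC replicate 2 (0.0518) or KD replicate 3 (0.104), at a mean of at least 5 FPKM (0.0864, 33 genes) and with RN18S1 as a covariate (0.392, median -0.10).

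Transcripts of oxidative phosphorylation were lower in KD morulae for 69 of 78 genes (median -0.34, camera adjusted p 0.00141; adjusted p = 0.828 with an estimated correlation), with 15 genes lower in the blocked fit; the call was lost without NC morula replicate 1 (0.124), NC replicate 3 (0.156) or KD replicate 2 (0.292). Genome activation genes, which embryos switch on around the 8/16-cell stage, were higher for 11 of 15 (median 0.26, camera adjusted p 0.00394; adjusted p = 0.549 with an estimated correlation), with ARGFX at 0.81 and POLR2A at 0.85; 5 rose and 1 fell when adjusted over the list alone, and 6 and 1 in the blocked fit. The camera adjusted p for this list was 0.0602 with RN18S1 as a covariate, where its median was 0.25.

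Interferon response genes were higher in KD morulae for 13 of 15 (median 0.84, camera adjusted p 8.42e-05). With an estimated correlation the camera adjusted p was 0.549. When adjusted over the list alone 2 rose, and 5 were higher in the blocked fit. Over the alternatives run the median of this list ran from 0.29 to 1.66. ISG15, a ubiquitin-like protein induced by interferon, stood at 3.75 FPKM in NC and 30.0 FPKM in KD (3.26, SE 0.73, adjusted p 0.0624), with IFI6 at 2.87, IFI27 at 2.31 and OAS1Y at 1.55. Markers of cumulus and granulosa cells were higher for 13 of 17 (median 0.66, camera adjusted p 0.00289; adjusted p = 0.566 with an estimated correlation; 3 higher and 1 lower in the blocked fit), with VIM at 1.80, CYP11A1 at 1.46, COL1A1 at 0.77 and SERPINE2 at -0.71. VIM stood at 3.72 FPKM in NC and 19.2 FPKM in KD, and the call for this list was lost without NC morula replicate 1 (0.0535), with quantile normalization (0.0562), at a mean of at least 5 FPKM (0.167, 6 genes) and with RN18S1 as a covariate (0.084, median 0.64).

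The remaining lists were not called by camera at the morula stage. The camera adjusted p-values were 0.0652 for p53 and apoptosis (blocked 0.0333, median 0.17), 0.0828 for DNA replication and cell cycle (blocked 0.0417, median -0.27), 0.12 for imprinted genes, 0.155 for blood and immune markers, 0.196 for oocyte transcripts, 0.406 for stress and heat shock and 0.463 for signalling genes. They were 0.579 for ribosomal proteins, 0.579 for glycolysis (median -0.13, mean 0.01), 0.825 for sperm and testis markers (median 0.07, mean -0.04) and 0.94 for ribosome biogenesis, whose median was -0.08 while the test pointed up. Of the oocyte list, MOS (1.42), BTG4 (0.88), KHDC3L (0.71) and BUB1B (-0.76) did not pass. The blocked fit called 8 replication genes lower, 3 p53 genes higher and 1 lower, 4 stress genes higher and 2 lower, 2 oocyte genes higher and 3 lower, and at most 4 genes of each other list in this paragraph. Of the list members named at the morula stage as not passing, all but H2AFY (blocked 0.193), BTG4 (blocked 0.0552) and the lineage genes already given passed in the blocked fit. None of the blocked list calls held with an estimated correlation (adjusted p of 0.273 or more).

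**Figure D4:**
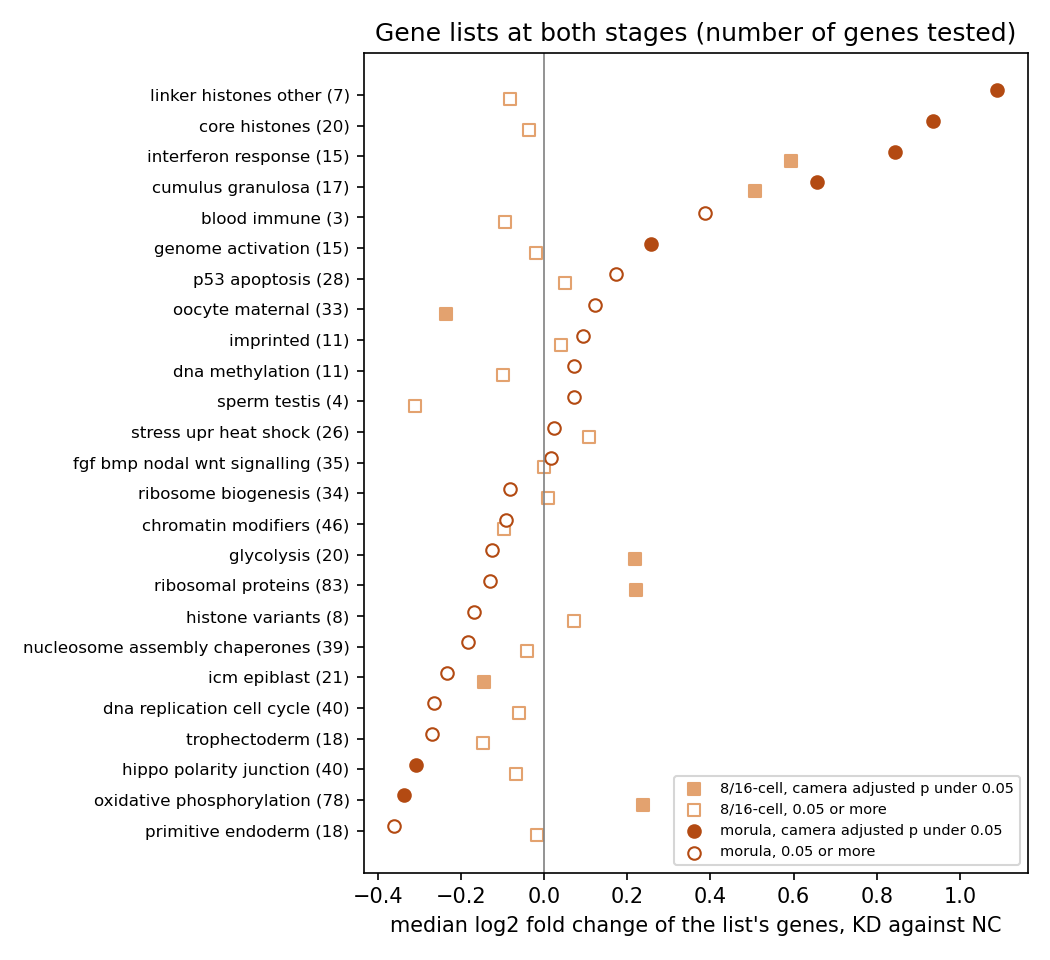
Median log2 fold change of KD against NC (x axis) for the 25 tested gene lists (y axis, number of genes tested in brackets) at the 8/16-cell stage (squares) and the morula stage (circles); filled symbols mark a camera adjusted p under 0.05 with the preset correlation. Other linker histones (1.09) and core histones (0.94) lie farthest right at the morula stage and at -0.08 and -0.04 at the 8/16-cell stage.

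From the 8/16-cell stage to the morula, 24 of 33 genes of the oocyte list fell in NC embryos, 2 rose and 7 did not pass (camera adjusted p 3.88e-11; adjusted p = 0.538 with an estimated correlation). LGALS3, a galactose-binding lectin, rose from 2.58 to 145 FPKM (log2 change 5.26, SE 0.46), and FN1, fibronectin, rose by 4.77, FBLN2 by 4.05, SPIC by 3.73 and OTX2 by 3.63. The oocyte growth factor BMP15 dropped from 57.5 to 0.873 FPKM (-4.96, SE 0.41), with OOSP2 at -5.87, MOS at -4.92, KPNA7 at -4.83 and BTG4 at -4.71. Of 78 oxidative phosphorylation genes 37 rose and 1 fell (2.83e-11), of 40 Hippo, polarity and junction genes 11 rose and 1 fell (0.00686), and of 18 primitive endoderm genes 8 rose (0.00686); for these 3 lists the adjusted p was 0.914 with an estimated correlation. Adjusted over the list alone, 26 oocyte genes fell, 44 oxidative phosphorylation genes rose, 11 Hippo genes rose and 8 primitive endoderm genes rose. In limma 3626 genes passed (1484 higher, 2142 lower in morulae), and 2355 passed between the KD stages (614 higher, 1741 lower). The 2 stages' columns seem to have been made apart, and the share of higher calls in KD moved from 26.1% to 52.7% with median scaling and from 26.1% to 81.6% with rescaling to an equal sum. The NC count was 1406 without NC 8/16-cell replicate 1 and 1662 without NC 8/16-cell replicate 2. The KD count was 789 and 693 without KD 8/16-cell replicate 1 or 2, and 1072 and 1504 without KD morula replicate 1 or 2.

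The difference between the KD effects of the stages was tested as an interaction. In limma 2 genes passed, MIR2887-1 and MIR2887-2, and 1104 had an unadjusted p under 0.05. The blocked fit called 32 genes (9 higher, 23 lower). That fit also pairs the 8/16-cell libraries by number, although same-numbered libraries of that stage correlated at only 0.056 and were not taken as pairs. The KD effects of the stages shared no library and correlated weakly across genes (Pearson r = 0.153, Spearman 0.111, 11761 genes, which are not independent replicates). Of the 82 genes that passed at the morula stage 55 had the same sign at the 8/16-cell stage, and 10 of the 82 had an unadjusted p under 0.05 there. At an unadjusted p under 0.05 59 genes were higher and 60 lower at both stages, while 23 were higher at the 8/16-cell stage and lower at the morula stage and 8 the other way; 1 fit gives both stages the same spread per gene, so these lists are not independent. SGK1 was among the higher genes of both stages (0.71 and 0.73). The correlation was 0.069 without KD 8/16-cell replicate 2 and -0.008 with RN18S1 as a covariate.

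Genes that changed between the NC stages were also compared with the KD effect at the morula stage. Genes that rose towards the NC morula had a median KD effect of -0.476, below the simulated range of -0.315 to 0.252 for unchanged groups sharing the same NC libraries. The simulated NC and KD libraries varied independently, without the pairing taken for the morulae. Of these genes 91.3% were negative, inside the simulated range of 17.9% to 92.9% (mean 58.8%). Genes that fell had a median of 0.239, inside the simulated range of -0.199 to 0.242. Across genes the KD effect and the NC stage change had r = -0.60, where the simulated groups gave a mean of -0.18 and a range of -0.72 to 0.55. The covariance was -0.269, with a simulated mean of -0.062 and a range of -0.334 to 0.267. At the 8/16-cell stage the correlation was 0.10, with a simulated mean of 0.23.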

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

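The tests of shared control libraries, of the shift left over after a share of day 4 embryos and of chance differences in stage between pools, and the RN18S1 covariate, were chosen after the results were seen; for the other tests here the deciding value had not been seen, although the histone, RN18S1 and stage values that prompted them had.

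The interaction test of the KD effect between the stages passed for 2 genes and, with the preset correlation, for 7 gene lists. With an estimated correlation the adjusted p of these 7 lists was 0.586 to 0.803. With fry, the shift to 1 side had an adjusted p of 0.605 to 0.694. The alternatives of leaving out a library and of scaling were not run for the interaction of lists. Rescaling to an equal sum moved the median interaction of all genes from -0.097 to 0.321. The fitted differences of log2 effects (morula minus 8/16-cell) were -14.81 for MIR2887-1 and -15.6 for MIR2887-2, which are listed at 0 in every library but the 2 KD 8/16-cell ones, so that these sizes depend on the pseudocount and bound nothing. Lists with a higher KD effect at the morula stage were other linker histones (median difference 1.26, camera adjusted p 3.7e-06), core histones (0.77, 6.35e-07), oocyte transcripts (0.40, 1.91e-04) and genome activation genes (0.33, 0.0257). Those with a lower effect were oxidative phosphorylation (-0.63, 2.39e-07), ribosomal proteins (-0.31, 0.00702) and primitive endoderm (-0.47, 0.0342). No single gene of these lists passed in limma without the block, where 1104 of all genes had an unadjusted p under 0.05. The blocked fit called 1 oocyte gene higher, H1FOO, and 2 primitive endoderm genes lower, FN1 and COL4A1. That fit also pairs the 8/16-cell libraries, whose numbers were not taken as pairs. H1FOO is the target itself and was low in both treatments at the morula stage. The groups of 2 or 3 libraries are too small for a test of single outlying libraries.

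The histone transcripts were higher in KD morulae by a mean of 0.93 over 27 genes (SE 0.26), and KD morulae also carried more RN18S1 (1.23). An earlier position along the change from 8/16-cell embryo to morula would account for 0.09 of it (95% interval -0.07 to 0.27), so the tables argue against this as the whole source. Carry-over of RNA without a poly(A) tail cannot be told apart from a KD effect. Most replicative histone transcripts lack such a tail, and H1F0 and H1FX transcripts have it. The slope on RN18S1 within groups, which does not use the pairs, accounts for 0.29 (-0.26 to 0.83). The difference left after it is 0.64 (-0.18 to 1.46). By pairs, the histone mean went from 2.58 to 3.84, from 3.43 to 4.04 and from 3.40 to 4.30. RN18S1 went from 2704 to 9053, from 2983 to 8553 and from 8611 to 11581 FPKM. These 3 pairs are too few to separate the explanations. With RN18S1 as a covariate the core histone median went from 0.94 to 0.55 (camera adjusted p 0.00117) and the linker histone median from 1.09 to 1.02 (0.000545), calls made with the preset correlation that are lost without the covariate at an estimated one (adjusted p = 0.529 with an estimated correlation), and NC morula replicate 3 had a histone mean of 3.40 at 8611 FPKM of RN18S1 where KD replicates 1 and 2 had 3.84 and 4.04 at 9053 and 8553 FPKM. A response of linker and core histone genes to the loss of H1FOO remains open as a hypothesis.

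On average, KD morulae lay nearer to the 8/16-cell libraries than NC morulae did. On a stage axis that holds neither library of a pair, the KD library lay below its NC partner in 3 of 3 pairs. The mean shift was 0.254 of the stage distance (SD 0.066). Positions overlapped between treatments, each on the axis of its own pair: KD replicate 1 lay at 0.856, NC replicates 2 and 3 at 0.737 and 0.814. Shared control libraries cannot create a shift on such an axis, but this shift is not told apart from chance (below). The covariance of -0.269 lies inside its simulated range, but the simulated NC and KD libraries varied independently, without the pairs. These tests therefore do not decide whether sharing is the whole source. A share of embryos with the profile of day 4 in the KD pools was estimated from genes that fall between the stages. It was 1.2%, 5.3% and 7.2% above the NC partners (upper 95% bounds 2.6%, 11.3% and 13.3%). At these bounds mixing would bring shifts of 0.045, 0.111 and 0.144 where 0.213, 0.22 and 0.33 were seen. A mean of 0.154 was left over (95% interval 0.054 to 0.254). The bounds rest on 52, 65 and 72 genes of KD replicates 1, 2 and 3 and hold no spread between libraries. That interval takes as independent 3 pairs whose axes share NC libraries. Delayed embryos that had already lost these transcripts would not be counted. The values therefore do not decide whether embryos of an earlier stage in the KD pools are the whole source. The gap from shares that rising genes give, chosen beforehand, was -49.5, -74.8 and -92.5 percentage points in KD. This gap was also 0.4, -61.8 and -42.1 in left-out NC morulae, and was not used. Chance differences in stage between pools cannot be told apart from a KD effect, since no exact test on 3 pairs can decide: the sign-flip p of 0.25 is the smallest it can give and the unpaired permutation p is 0.3 where 0.1 is the smallest, while a 95% interval of the mean (0.091 to 0.417) leaves out 0 but takes as independent 3 differences whose axes share NC libraries. A delay of KD embryos may be a candidate explanation, and it was not tested apart from the RN18S1 difference.

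For the count at the morula stage, 1 of the 10 splits of the 6 morula libraries into 3 and 3, the real one, gave as many genes as 82, and the highest other split gave 2. With 10 splits the share is never under 0.1, too few for a share under 0.05. In the blocked fit the real split gave 1398 genes and the highest of the other splits that part all 3 pairs gave 1. Only 4 splits part all 3 pairs, the real one among them, so this comparison is weaker than that of the 10. A KD difference would also widen the spread within the groups of the other splits. Their low counts are therefore no measure of chance in either fit.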

How the results depend on the processing

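The RN18S1 covariate, keeping repeated symbols, leaving out the MIR2887 pair with rescaling, and the block without 1 pair were chosen after seeing the data; the other alternatives were fixed before. Counts are genes past the threshold in limma, and the cause was not tested unless given. At the 8/16-cell stage the count of 2 became 11 without a filter, 4 rescaled to an equal sum, 1 with the stage alone and 4 with RN18S1 as covariate. It was 0 without the MIR2887 pair, rescaled (412 unadjusted), where only the absence of that pair was fixed in advance. Without 1 morula library it was 2 or 3. At the morula stage the count of 82 became 6 without a filter, 139 at a mean of at least 5 FPKM (fewer genes tested), 3 rescaled, 0 with the stage alone (fewer libraries for the spread, 2131 unadjusted), 1398 with the replicate block, 181 with robust moderation, 367 with library weights, 0 with RN18S1 as covariate (1243 unadjusted) and 9 without the MIR2887 pair, rescaled. The block without pair 1, 2 or 3 gave 0 (2449 unadjusted), 393 and 18 genes, and leaving out 1 library gave 0 to 527 (1487 to 2844 unadjusted). The share of higher genes was 20.7% in the fit reported, 40.6% with quantile normalization (28 higher, 41 lower) and 30.8% with median scaling (24 and 54). The interaction count of 2 became 32 with the block, 4 with RN18S1 as covariate, 0 without the MIR2887 pair, rescaled (825 unadjusted), 2, 5 and 7 with the block without pair 1, 2 or 3, and 2 to 6 without 1 library. The NC stage count of 3626 became 2062 with a 2-fold minimum and 1406 to 3657 without 1 library. The KD stage count of 2355 became 1402 rescaled, 1330 without the MIR2887 pair, rescaled, 1245 with a 2-fold minimum and 693 to 2698 without 1 library. H1FOO at the 8/16-cell stage kept its sign. Among fits of all 10 libraries it passed in limma when rescaled (-5.25, adjusted p 0.0162) and with the replicate block (-4.22, 0.0107). Without 1 library its log2 difference was -5.28 to -3.15, and over all alternatives it was -6.03 to -2.47. H1FOO at the morula stage kept its sign and passed in none of 28 alternatives. The correlation of KD effects between stages was -0.008, reversed, with RN18S1 as covariate and 0.069 to 0.216 without 1 library; that with the NC stage change was -0.673 to -0.531 without 1 library. The 7 lists called at the morula stage became 11 with library weights and 4 to 9 without 1 library, and the 7 called at the 8/16-cell stage became 4 to 7 without 1 library. The median of ribosomal proteins at the 8/16-cell stage was -0.02 with quantile normalization and 0.00 without KD 8/16-cell replicate 1, both with the test pointing down, and up to 0.48 without 1 library. Over all alternatives the list calls kept the direction of the test and their side of the threshold in 176 of 196 cases at the 8/16-cell stage and 183 of 196 at the morula stage, and the named genes in 800 of 806 and 574 of 836, with 199 morula cases that lost and 54 that gained a call. Of the named genes, 5 cases at the 8/16-cell stage and 9 at the morula stage changed sign, all of genes that passed in neither fit. With RN18S1 as covariate these were SOX2 (0.19), KRT8 (0.32) and KRT18 (0.07) in morulae, rescaled KRT8 at the 8/16-cell stage (-0.18), and in morulae TFAP2C with library weights (0.00) and with the block without pair 2 (-0.08). Without 1 library the values ran from -0.54 to 0.25 for NANOG, -0.57 to 0.07 for POU5F1 and -0.01 to 0.40 for KRT8 at the 8/16-cell stage, and from -0.34 to 0.01 for SOX2, -0.05 to 0.04 for TFAP2C and -1.08 to 0.06 for KRT18 in morulae. At the 8/16-cell stage, same-numbered libraries correlated at 0.056, so the numbers were not taken as pairs, and the block gave 3 genes, H1FOO added; at the morula stage it changed no call beyond those given with the results. Read depth is unknown, so a gene listed at 0 is not shown to be absent.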

Other observations

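The genes and the family scan of this part were chosen after their values were seen. Among the 65 genes that fell in KD morulae were further genes of cell junctions and the cell cortex: DSG2, a desmosomal cadherin, went from 40.1 to 13.5 FPKM (log2 change -1.55, SE 0.22, limma adjusted p 0.0298), TIAM1, an activator of the GTPase RAC1, changed by -1.52 (adjusted p 0.0427), the scaffold gene DLG3 by -1.19 (0.0427), the actin-capping gene CAPG by -1.33 (0.0442) and ACTR3, part of the complex that branches actin, by -0.77 (0.0486). Mitochondrial enzymes that fell were SUCLG2 of the citric acid cycle (-1.58, adjusted p 0.0377), ALDH6A1 of valine breakdown (-1.40, 0.0382), DLAT of the pyruvate dehydrogenase complex (-1.35, 0.0374) and ACAT1 of ketone body metabolism (-0.9963, 0.0278), as did the mitochondrial fusion gene MFN1 (-1.24, 0.0412). These genes are not a list fixed beforehand, and no theme was tested for them.

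Chromatin genes that fell were HMGN1, a nucleosome-binding protein (-1.13, limma adjusted p 0.0427), CBX3, which binds methylated histone H3 (-1.03, 0.0468), and TERF1 of telomeres (-1.02, 0.0278). In lysosomes, LAMP2 (-0.87, 0.0486) and the proton pump subunit ATP6V1A (-0.89, 0.0427) fell. SNAP25, a gene of vesicle fusion, fell in KD morulae (-1.14, 0.0427) and had a log2 difference of -0.89 at the 8/16-cell stage, which did not pass there. The RN18S1 level of the KD morulae was higher by 1.23, as given for the histone genes, and none of these genes passed with it as a covariate, where limma called 0 genes (1243 at an unadjusted p under 0.05). The calls ended as the SE widened and most changes shrank: DSG2 went from -1.55 (SE 0.22) to -1.40 (SE 0.30), SUCLG2 from -1.58 (0.26) to -1.51 (0.36), TIAM1 from -1.52 (0.28) to -1.12 (0.33) and HMGN1 from -1.13 (0.21) to -0.94 (0.27), while CAPG went from -1.33 (0.25) to -1.51 (0.33).

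A scan of 180 gene families by the root of their symbols found 1 family past the threshold at the morula stage, the HIST genes, with 23 of 24 higher in KD (median 0.999, camera adjusted p 2.53e-09; adjusted p = 0.985 with an estimated correlation), a family that overlaps the core and linker histone lists. At the 8/16-cell stage no family passed with camera, where the lowest adjusted p was 0.0593, for RPL and SOX genes.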
